A study of Mus musculus with 96 samples.

How the data were processed

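Total RNA of whole spleen and whole blood of 48 mice was measured on 96 Illumina bead arrays, after globin removal and amplification to labelled cRNA per the labels' protocols. In experiment I RNA was isolated with Ambion kits and blood RNA was further purified with lithium chloride, and in experiment II Qiagen kits and stabilising tubes or solution were used. The strains, tissues, days and experiments were taken from the labels, and spleen and blood of a mouse were paired by the experiment and mouse number in the titles, which gave 48 mice with both tissues and matching genotype and day.

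The deposited table holds probe intensity on a linear scale for 25697 probes, where log2 values had been assumed before it was read, so log2 was taken first. Limma is the only tool named in the submitters' processing notes, and its version is not stated. The values showed that all 48 spleen arrays share nearly 1 distribution (minimum 45.0, median 82.2, maximum 38405) and all 48 blood arrays another (minimum 46.2, median 73.4, maximum 43230). At the same rank, arrays differed from the first array of their tissue by at most 3.73 intensity units in spleen and 1.05 in blood. The arrays had thus been quantile normalised within a tissue over both experiments, and background had not been subtracted to 0. Background correction and any arrays left out upstream are not given in the sources used here. The highest correlation between any 2 arrays of a tissue was 0.997, so no array was present in duplicate. Arrays have no sequencing depth, and their number limits the precision.

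Of the probes, 23978 carried 1 gene symbol, 0 carried several and 1719 had no gene named here. Entrez identifiers of 23962 probes matched the reference gene table of assembly GRCm38.p6, which was used for names and gene order only. For each gene the probe with the highest mean over all arrays was kept, which gave 16593 genes, 4777 of them with more than 1 probe. All probes of Ncf1 were shown, and probes without a gene were tested apart.

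Each tissue was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the 4 groups of genotype and day and the experiment as terms. Contrasts gave the genotype difference at day 15, at day 44 and averaged over both days, the difference of day 44 against day 15 averaged over genotypes, and the genotype by day interaction. For the comparison of tissues the same model was fitted to the difference of spleen and blood of each mouse. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, within a comparison. Each fit was repeated within each experiment. Levels are means after removal of the difference between the experiments.

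The comparisons, the threshold, 27 gene lists (814 distinct symbols, 680 measured) and the rule for naming genes were fixed before the data were examined. The rule named Ncf1 and the NADPH oxidase genes, the 10 largest rises and falls among called genes with the same sign in both experiments, up to 4 called members of each list with the smallest adjusted p, and the 5 genes with the smallest p where fewer than 5 passed. A part of these genes is given. The lists were NADPH oxidase, Ncf1 neighbourhood, type I interferon, interferon-gamma, neutrophil granule and precursor, mature neutrophil, monocyte and macrophage, B cell, plasma cell, germinal centre and T follicular helper, T cell, T helper, NK and cytotoxic lymphocyte, dendritic cell, erythroid, platelet and megakaryocyte, cell cycle, inflammatory cytokine and NF-kB, antioxidant and NRF2 target, complement, MHC class II, ER stress, immediate early and heat shock, exocrine pancreas, adipose, sex-linked, and stroma and endothelium. Lists were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Counts adjusted over the list alone apply the adjustment to the list's measured genes.

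Alternatives were every probe, genes above the median level, quantile normalisation again, arrays centred on their median, no experiment term, either experiment alone, eBayes with trend and robust, array weights, 1 fit of all arrays with the mouse as a random block (statmod 1.5.0), and the compared groups alone. Chosen after seeing the data were normexp background correction with an offset of 50, experiment by group terms, and the removal of arrays whose mean over the exocrine pancreas list exceeded the median array of the tissue by more than 1 log2 unit. The data.table package had version 1.17.8. For each comparison 100 splits of the samples, the real one included, were drawn with the seed 1 by permuting genotype within day, or day over all mice. Another 100 were drawn by permuting genotype within day and experiment, or day within genotype and experiment.

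The steps were tested on simulated data with the same groups and experiments, with 100 changed genes per size among 16593. Noise was drawn independently for each gene and array, with the same SD in both experiments. The false calls below therefore do not cover genes that vary together or experiments of unequal spread. For the genotype in spleen over both days 95% of changes of 0.5 log2 units and 100% of changes of 1 log2 unit were recovered, with 12 false calls. In blood over both days the shares were 92% and 99%, with 9 false calls, and for the interaction in spleen 76% and 95%, also with 9.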

Results

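RNA from spleen and blood of 48 male mice, taken in the course of collagen induced arthritis, was measured on 96 Illumina bead arrays, 1 array per tissue and mouse. Mice of the BQ background were either wild type or carried the Ncf1m1J mutation. Ncf1 encodes a cytosolic subunit of the phagocyte NADPH oxidase, the enzyme complex with which neutrophils and macrophages make reactive oxygen species. Tissues were taken 15 or 44 days after immunisation from different mice, which gave 8 groups of 12 arrays (tissue, genotype and day). Each group held 6 mice of experiment I and 6 of experiment II, which used different RNA isolation kits. No unimmunised mice were among the arrays used here. The values of every spleen array had a median intensity of 82.2 and a maximum of 38405, and those of every blood array a median of 73.4 and a maximum of 43230. The number of arrays limits the precision. Differences are given as log2 differences ± standard error from limma, with 12 mice per genotype at a single day and 24 over both days, and levels as log2 intensity ± SD.

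The first question was how far the mutation changed the transcript of Ncf1 itself. In spleen the level of Ncf1 was 7.33 ± 0.20 (SD, n = 12) in wild type and 6.43 ± 0.15 in mutated mice at day 15, and 7.22 ± 0.25 and 6.40 ± 0.22 at day 44. In blood it was 6.81 ± 0.28 in wild type and 6.33 ± 0.20 in mutated mice at day 15, and 6.86 ± 0.23 and 6.26 ± 0.24 at day 44. Over both days Ncf1 was lower in mutated spleen (log2 difference -0.86 ± 0.06, adjusted p = 1.9e-14) and lower in mutated blood (-0.55 ± 0.07, adjusted p = 1.1e-06). In experiment I the means of mutated blood, 6.06 at day 15 and 5.99 at day 44, lay below the array median of 6.20, and those of mutated spleen, 6.36 and 6.25, lay at or below the array median of 6.36, so the size of the fall was limited by background in both tissues. In spleen the highest mutated mouse lay below the lowest wild type mouse in each experiment, at 6.57 against 6.66 in experiment I and 6.88 against 7.04 in experiment II. In blood 0 of 12 mutated mice lay above the lowest wild type mouse in experiment II and 10 of 12 in experiment I. A second Ncf1 probe, ILMN_1228585, lay between 5.85 and 6.05 in the mean of every group and experiment and did not differ (-0.01 ± 0.03 in spleen, adjusted p = 0.965). Other oxidase subunits did not pass in mutated spleen, among them Cybb (-0.02 ± 0.03), Cyba (-0.16 ± 0.12), Ncf4 (-0.03 ± 0.07) and Rac2 (-0.33 ± 0.14). The level of the Cybb probe is not given here, so a probe at background is not excluded for this gene. Prkcd, the kinase that phosphorylates the Ncf1 protein, fell by 0.31 ± 0.07 (adjusted p = 0.0012).

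**Figure D1:**
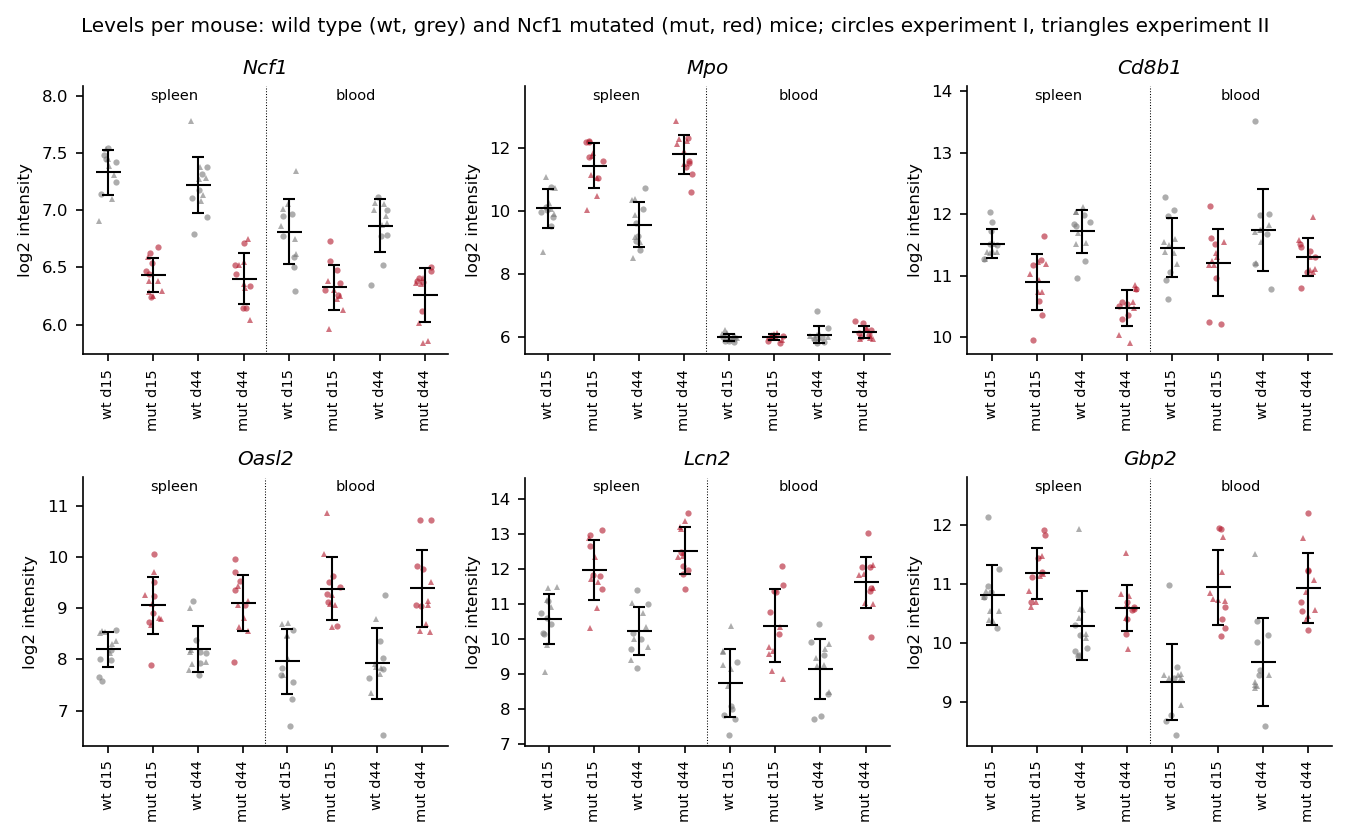
Log2 intensity of 6 genes in every mouse after removal of the mean difference between the experiments, with the mean and SD of each group of 12 mice; circles are experiment I and triangles experiment II. Spleen Mpo lies at 10.09 and 9.57 in wild type and at 11.45 and 11.80 in mutated mice at day 15 and day 44, while blood Mpo stays near 6.0 to 6.2 in the 4 blood groups.

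Over both days, mutated spleens held more transcripts of granulocyte precursors, red cell precursors and dividing cells and fewer of T and B lymphocytes. Mpo, an enzyme stored in primary granules of neutrophil precursors, was 3.47-fold higher (1.79 ± 0.19, n = 24 per genotype, adjusted p = 5.4e-09). The granule proteases Prtn3 (1.94 ± 0.22), Ctsg (1.92 ± 0.21) and Elane (1.66 ± 0.20) and the secondary granule genes Ltf (1.85 ± 0.22), Lcn2 (1.84 ± 0.21), Ngp (1.69 ± 0.22) and Camp (1.36 ± 0.17) rose alongside it. Cd8b1, a chain of the CD8 coreceptor of cytotoxic T cells, was 1.91-fold lower (-0.93 ± 0.10, adjusted p = 5.4e-09). Fcer2a, which encodes CD23 of mature B cells, was 1.83-fold lower (-0.87 ± 0.12, adjusted p = 2e-06).

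Limma called 1748 of 16593 genes in this comparison, 939 higher and 809 lower, and all 1748 had the same sign in both experiments. Calling genes in a fit of both experiments favours the same sign in each, here and in later counts of this kind, so it is no replication. Of the 581 genes called in experiment I alone, 577 had the same sign in experiment II. Of the 22 measured genes of the neutrophil granule and precursor list, 20 rose and 0 fell (20 when adjusted over the list alone), with a median of 1.32. The mature neutrophil list had 14 of 25 genes higher and 0 lower (17 adjusted over the list alone), among them S100a9 (1.22 ± 0.16) and the receptor Trem3 (1.15 ± 0.13), and its median was 0.28. Of 40 erythroid genes 31 rose and 0 fell (33 adjusted over the list alone), at a median of 0.67, including the regulators Tal1 (1.01 ± 0.17) and Nfe2 (0.98 ± 0.14), the transferrin receptor Tfrc (0.95 ± 0.17) and the membrane skeleton gene Ank1 (1.13 ± 0.20). Of 49 cell cycle genes 39 rose and 0 fell (41 rose and 1 fell adjusted over the list alone), at a median of 0.60, with the replication genes Mcm10 (0.84 ± 0.13) and Cdc45 (0.76 ± 0.11) and the spindle checkpoint gene Bub1b (0.53 ± 0.07). Platelet and megakaryocyte genes rose in 12 of 24 cases and fell in 1 (15 and 1 adjusted over the list alone), such as Vwf (0.57 ± 0.08) and Treml1 (0.64 ± 0.11).

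Lymphocyte genes moved the other way. Of 23 T cell genes 0 rose and 18 fell (18 adjusted over the list alone), at a median of -0.48, including Cd2 (-0.62 ± 0.08), Cd28 (-0.57 ± 0.08), Cd3g (-0.69 ± 0.11) and the homing receptor Ccr7 (-0.37 ± 0.05). Of 19 B cell genes 16 fell and 0 rose (18 adjusted over the list alone), at a median of -0.41, including Vpreb3 (-0.78 ± 0.12), Ms4a1 (-0.39 ± 0.06), Cd79a (-0.76 ± 0.18) and the BAFF receptor Tnfrsf13c (-0.56 ± 0.09). NK and cytotoxic lymphocyte genes fell in 6 of 21 cases (7 adjusted over the list alone), among them Klrd1 (-0.57 ± 0.07) and Ctsw (-0.64 ± 0.11). In the dendritic cell list 4 of 19 genes fell and 1 rose (7 and 2 adjusted over the list alone), with the plasmacytoid markers Siglech (-0.79 ± 0.13) and Tcf4 (-0.26 ± 0.05) lower. Germinal centre and T follicular helper genes fell in 4 of 15 cases (7 adjusted over the list alone), for example Cd83 (-0.56 ± 0.09), Icos (-0.28 ± 0.07) and Sh2d1a (-0.31 ± 0.05). Cd209b, a lectin of marginal zone macrophages, fell by 0.70 ± 0.11.

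Camera called 18 of the 27 fixed gene lists in spleen over both days, and 12 kept the call with an estimated correlation. Beside the lists above these 12 were the NADPH oxidase list, with Ncf1 and Prkcd lower among 14 genes and a median of -0.07, and the antioxidant and NRF2 target list, with 7 of 32 genes higher and 2 lower (9 and 2 adjusted over the list alone). The oxidase list holds the mutated gene itself, so its call says little about the other oxidase genes. Prdx2 rose by 0.53 ± 0.11 and Tkt by 0.31 ± 0.06, while Ephx1 fell by 0.48 ± 0.07. Type I interferon genes rose in 10 of 45 cases and fell in 2 (14 and 4 adjusted over the list alone), among them Oasl2 (0.88 ± 0.14), Isg15 (0.73 ± 0.14), Oas1g (0.39 ± 0.06) and, lower, Sp100 (-0.30 ± 0.07), with adjusted p = 0.0974 for the list with an estimated correlation. Interferon-gamma-inducible genes rose in 5 of 31 cases and fell in 1 (5 and 1 adjusted over the list alone), with Igtp at 0.53 ± 0.10, Gbp7 at 0.34 ± 0.06 and Ciita at -0.21 ± 0.06, and adjusted p = 0.426 with an estimated correlation. The T helper list had 5 of 20 genes lower and 1 higher, including Gata3 (-0.25 ± 0.05) and Tbx21 (-0.22 ± 0.06), with adjusted p = 0.075 with an estimated correlation. In the MHC class II list 4 of 20 genes fell, including H2-Ob (-0.51 ± 0.08) and Cd40 (-0.29 ± 0.08), with adjusted p = 0.0665 with an estimated correlation. Stroma and endothelium genes fell in 3 of 28 cases (10 adjusted over the list alone), including Dcn (-0.41 ± 0.09) and Pecam1 (-0.25 ± 0.07), with adjusted p = 0.104 with an estimated correlation.

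Exocrine pancreas genes, which the spleen itself hardly expresses, had a median of -0.50 over 26 genes, of which 0 rose and 0 fell (0 and 0 adjusted over the list alone). Camera gave adjusted p = 0.0016 for them, and adjusted p = 0.576 with an estimated correlation. Their median was -1.08 in experiment I and 0.06 in experiment II. Pancreatic transcripts lay over 1 log2 unit above the median array in 4 spleen arrays, 3 wild type and 1 mutated, all of experiment I. Without these arrays 1429 genes were called, 20 of 22 granule genes rose, 18 of 23 T cell genes fell, and the median of the pancreas list was -0.01.

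The other lists were not called in spleen over both days. Monocyte and macrophage genes rose in 3 of 28 cases, among them F13a1 (0.74 ± 0.10) and Fcgr4 (0.57 ± 0.10), but their median was -0.06, their mean 0.01 and the direction of the test upward. In the inflammatory cytokine and NF-kB list Saa3 (0.92 ± 0.15) and Tnfaip2 (0.60 ± 0.08) rose and Nfkbia (-0.39 ± 0.09) and Ltb (-0.52 ± 0.13) fell among 35 genes, and the median of -0.01 and the mean of 0.01 differed in sign. ER stress genes rose in 3 of 23 cases and fell in 1, with Asns at 0.96 ± 0.18 and Ppp1r15a at 0.81 ± 0.17. Immediate early and heat shock genes fell in 3 of 27 cases, including Klf2 (-0.65 ± 0.12) and Zfp36 (-0.34 ± 0.08). Plasma cell genes fell in 3 of 21 cases, including Irf4 (-0.37 ± 0.07) and Mzb1 (-0.27 ± 0.09). Complement had C6 higher (0.30 ± 0.09) and Cd55 lower (-0.39 ± 0.10) among 23 genes, and adipose had Slc2a4 higher (0.29 ± 0.06) and Scd1 lower (-0.32 ± 0.08) among 17. None of 4 sex-linked genes was called, with a median of 0.01 and a mean just below 0. Around Ncf1 on chromosome 5, Lat2 (-0.38 ± 0.08), Upk3b (-0.44 ± 0.10) and Castor2 (-0.16 ± 0.04) were among 4 genes that fell and Mettl27 (0.17 ± 0.04) was the 1 that rose, out of 42.

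**Figure D2:**
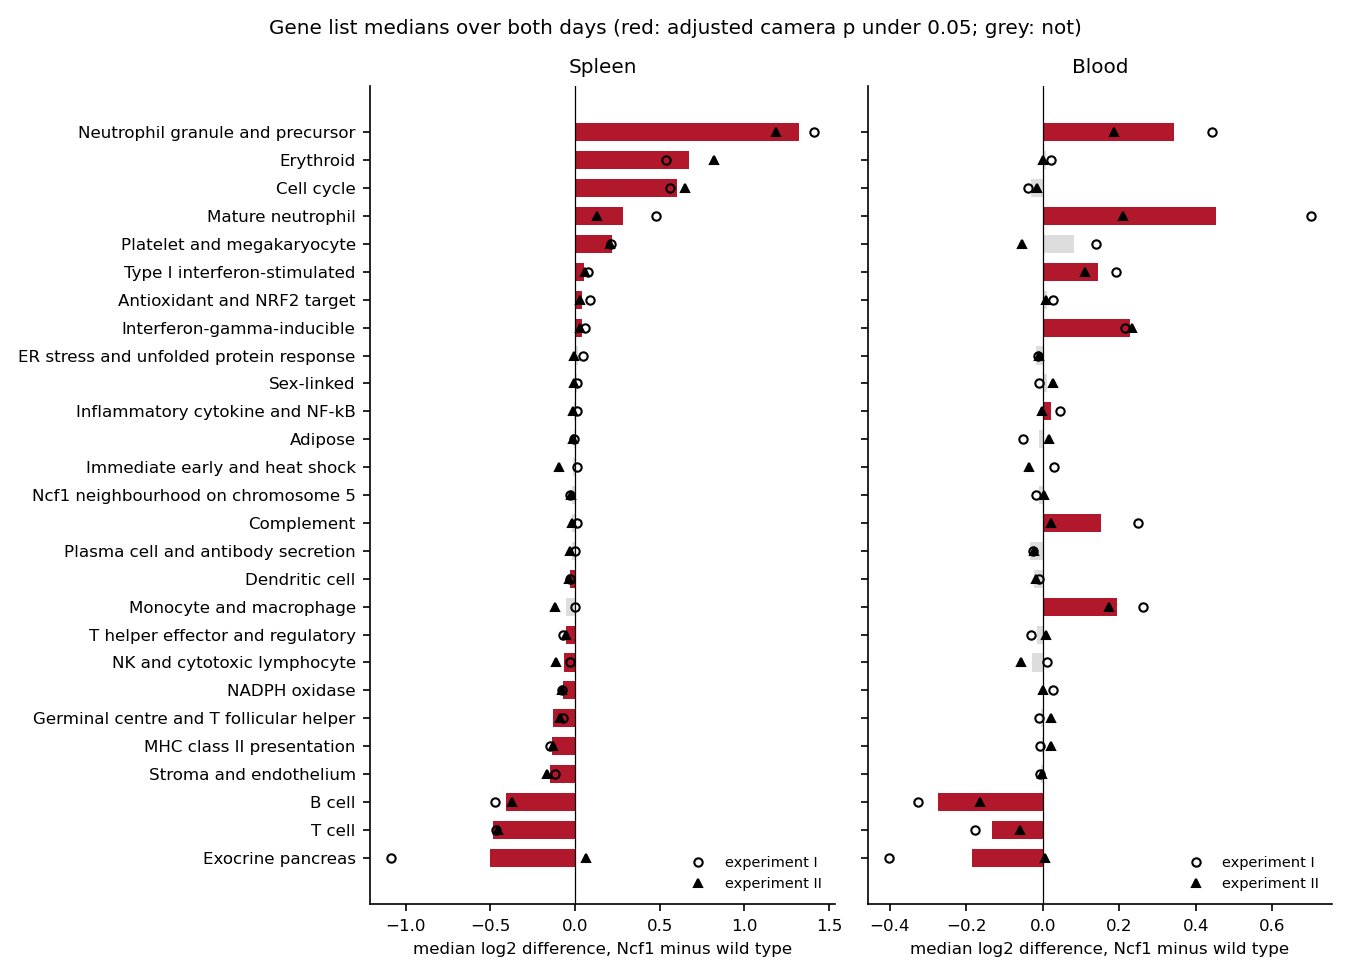
Median log2 difference between mutated and wild type mice of each of 27 fixed gene lists over both days (bars) and in each experiment (symbols), in spleen and in blood; red bars mark an adjusted camera p under 0.05. The granule list reaches 1.41 in experiment I and 1.19 in experiment II in spleen, whereas the pancreas list reaches -1.08 in experiment I and 0.06 in experiment II.

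At day 15, the early time point, spleens of mutated mice already held more Mpo, 2.56-fold (1.36 ± 0.27, n = 12 per genotype, adjusted p = 0.0079). Prtn3 (1.51 ± 0.31), Ltf (1.49 ± 0.30), the erythroid gene Ank1 (1.26 ± 0.29) and the mitotic gene Prc1 (1.09 ± 0.22) rose as well. Cd8b1 fell by 0.62 ± 0.14, Cd3g by 0.61 ± 0.15 and the plasmacytoid dendritic cell gene Siglech by 0.70 ± 0.19. Limma called 410 genes, 320 higher and 90 lower, and 142 in experiment I alone against 2 in experiment II alone, where 139 of the 142 had the same sign. Granule genes rose in 17 of 22 cases (17 adjusted over the list alone), with medians of 1.36 in experiment I and 0.57 in experiment II. The counts of higher genes were 8 of 25 for mature neutrophils (13 adjusted over the list alone), 24 of 40 for erythroid cells (30), 28 of 49 for the cell cycle (39) and 4 of 24 for platelets (11). T cell genes fell in 9 of 23 cases (17 adjusted over the list alone) and B cell genes such as Ms4a1 (-0.34 ± 0.08) in 4 of 19 (12). Camera called 17 lists, of which 9 kept the call with an estimated correlation. Among those that did not, Oasl2 rose by 0.86 ± 0.20 and 4 of 45 type I interferon genes rose, with adjusted p = 0.239 with an estimated correlation, and 2 of 31 interferon-gamma genes, including Gbp7 (0.37 ± 0.09), rose, with adjusted p = 0.276 with an estimated correlation. The germinal centre list had adjusted p = 0.0568, the NADPH oxidase, NK and stroma lists each 0.0898, the MHC class II list 0.141 and the pancreas list 0.546 with an estimated correlation. Without the arrays with pancreatic transcripts 33 genes were called, 5 of 22 granule genes, 0 of 40 erythroid genes and 2 of 49 cell cycle genes rose, the granule median was 0.97 against 0.99 with all arrays, and the antioxidant list had adjusted p = 0.0602 with an estimated correlation against 0.0349.

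At day 44, the later time point, granule genes were higher and T cell genes lower in mutated spleen. Ctsg was 5.4-fold higher (2.43 ± 0.30, n = 12 per genotype, adjusted p = 2.9e-07), Mpo 4.69-fold (2.23 ± 0.27) and Lcn2 4.92-fold (2.30 ± 0.30), and the neutrophil integrin gene Itgb2l rose by 1.63 ± 0.18. Cd8b1 was 2.37-fold lower (-1.25 ± 0.14, adjusted p = 8.7e-08), Fcer2a 2.14-fold lower (-1.10 ± 0.18), and the T cell surface gene Cd6 fell by 0.81 ± 0.14. Limma called 861 genes, 512 higher and 349 lower, of which 861 had the same sign in both experiments. Experiment I alone gave 52 calls and experiment II alone 1008, of which 957 had the same sign in experiment I. Granule genes rose in 19 of 22 cases (20 adjusted over the list alone) at a median of 1.63, mature neutrophil genes such as S100a8 (1.41 ± 0.21) in 13 of 25 (15), erythroid genes such as Nfe2 (0.97 ± 0.20) in 16 of 40 (27), cell cycle genes such as Bub1b (0.57 ± 0.10) in 31 of 49 (38) and platelet genes in 8 of 24 (12). T cell genes fell in 16 of 23 cases (18 adjusted over the list alone) at a median of -0.63 and B cell genes such as Vpreb3 (-0.91 ± 0.17) in 10 of 19 (16). Klrd1 (-0.63 ± 0.11), Gata3 (-0.38 ± 0.08) and H2-Ob (-0.59 ± 0.12) also fell. Of 17 camera calls 10 remained with an estimated correlation, while the type I interferon list, with Oas1g at 0.49 ± 0.08, had adjusted p = 0.0881 with an estimated correlation. The T helper and antioxidant lists each had adjusted p = 0.0545, the MHC class II list 0.0729, the dendritic cell list 0.124, the stroma list 0.281 and the pancreas list 0.733 with an estimated correlation. Without the arrays with pancreatic transcripts 724 genes were called, and the erythroid and germinal centre lists had adjusted p = 0.0568 and 0.0552 with an estimated correlation, against 0.0426 for each with all arrays.

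Day 15 and day 44 did not share mice, and they had 257 higher genes in common against 9.87 expected if independent, and 59 lower genes against 1.89. Both days came from 1 fit with a shared estimate of each gene's spread, however. Their calls are therefore linked, and independence is not the value expected without a shared effect. Whether the genotype effect itself changed between the days was tested with the genotype by day interaction, for which limma called 0 genes in spleen, 363 having an unadjusted p under 0.05. The counts with trend and robust eBayes, with array weights and with the mouse as a random block were 0 as well. The genes with the smallest unadjusted p were Ccno (0.46 ± 0.12), Mapk13 (0.48 ± 0.13), Ankrd33b (0.23 ± 0.06), Dusp4 (-0.23 ± 0.06) and Olfr998 (-0.19 ± 0.05), none past the threshold. Camera called 3 lists. The granule list had an interaction median of 0.67 (adjusted p = 0.073 with an estimated correlation), with 0.08 in experiment I and 1.23 in experiment II. The T cell list had a median of -0.24 (adjusted p = 0.073 with an estimated correlation), with -0.01 in experiment I and -0.50 in experiment II, and the mature neutrophil list one of 0.09 (adjusted p = 0.436 with an estimated correlation).

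Between day 15 and day 44, averaged over the genotypes, single B cell and interferon-induced genes fell and mitotic ones rose in spleen, while 0 of the 11 lists that camera called kept the call with an estimated correlation (adjusted p = 0.196 for B cell, 0.172 for type I interferon and 0.542 for cell cycle genes). Cd79a, a signalling chain of the B cell receptor, fell by 0.93 ± 0.18 (n = 24 per day, adjusted p = 7.7e-04) and Fcer2a by 0.78 ± 0.12. Ifit3 (-0.55 ± 0.08), Oasl1 (-0.36 ± 0.05) and Siglec1 (-0.45 ± 0.07), which interferon induces, fell, with negative values in both experiments. The mitotic kinase Plk1 rose by 0.96 ± 0.19, with 1.47 in experiment I and 0.45 in experiment II, and the kinesin Kif22 by 0.84 ± 0.19. Limma called 3799 genes, 1905 higher and 1894 lower, but 5111 in experiment I alone and 1 in experiment II alone. Of the 5111 genes, 3487 had the same sign in experiment II, where their median change was 0.04 against 0.41 in experiment I, and a day by experiment term called 2457 genes. Without the arrays with pancreatic transcripts 1719 genes were called.

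B cell genes fell in 13 of 19 cases between the days (14 fell and 1 rose adjusted over the list alone), type I interferon genes in 19 of 45 with 3 higher (23 and 3), and stroma genes such as Col4a2 (-0.65 ± 0.14) and Mgp (-0.49 ± 0.10) in 16 of 28 with 1 higher (18 and 1). MHC class II genes such as Cd74 (-0.71 ± 0.15) and H2-DMa (-0.59 ± 0.12) fell in 10 of 20 cases, NK genes such as Klrg1 (-0.30 ± 0.05) in 8 of 21, interferon-gamma genes in 11 of 31, macrophage genes such as Vcam1 (-0.46 ± 0.09) and Mrc1 (-0.41 ± 0.09) in 10 of 28, and germinal centre genes in 3 of 15. Cell cycle genes rose in 21 of 49 cases (23 adjusted over the list alone), erythroid genes in 9 of 40 and granule genes in 5 of 22. For the other called lists the adjusted p with an estimated correlation was 0.196 for each of the stroma, MHC class II and NK lists, 0.442 for germinal centre, 0.607 for interferon-gamma and macrophages, 0.627 for erythroid and 0.738 for granule genes. Outside these lists Rac2 (-0.57 ± 0.14), Arhgdib (-0.43 ± 0.08), Tnf (-0.37 ± 0.07), Lbh (-0.97 ± 0.20) and Ly6e (-0.80 ± 0.15) fell and the selenoprotein gene Msrb1 (1.13 ± 0.24) rose. Ncf1 did not pass (-0.07 ± 0.06).

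**Figure D3:**
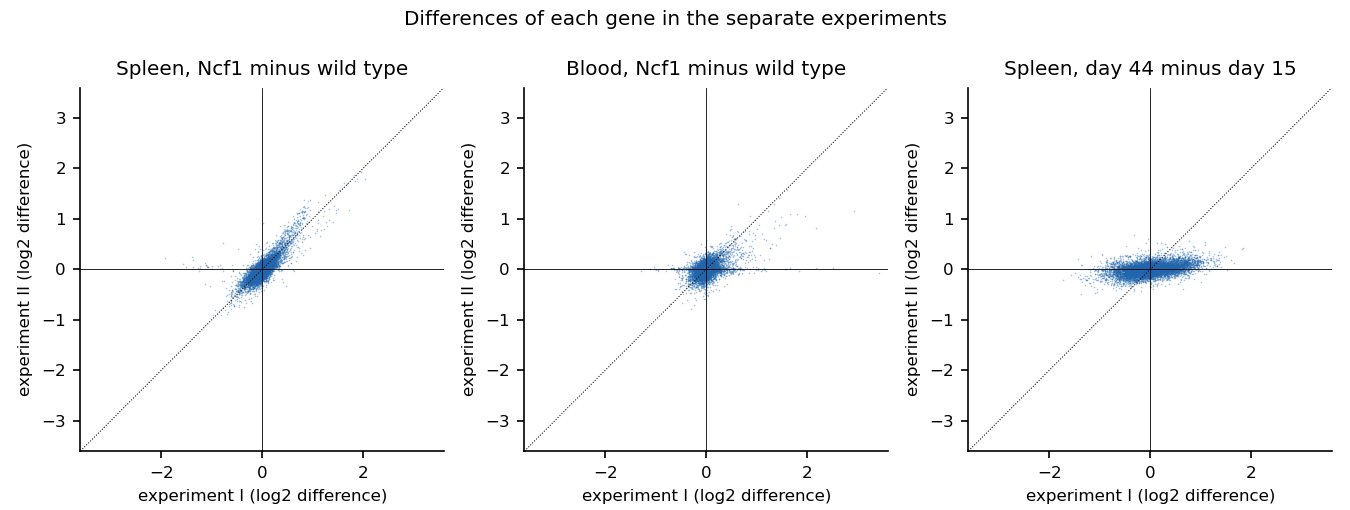
Log2 differences of 16593 genes in experiment I (horizontal axis) and experiment II (vertical axis), 1 point per gene, for the genotype in spleen, the genotype in blood and the day in spleen. Across genes, which are not independent replicates, r is 0.80, 0.48 and 0.39.

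In blood over both days, mutated mice had more transcripts of interferon-induced genes, neutrophils and monocytes. Lcn2, a neutrophil granule and acute phase gene, was 4.13-fold higher (2.05 ± 0.26, n = 24 per genotype, adjusted p = 1.1e-06), with 2.93 in experiment I and 1.16 in experiment II. The interferon-induced GTPase Gvin1 was 3.01-fold higher (1.59 ± 0.19, adjusted p = 5.6e-07), Oasl2 2.72-fold (1.45 ± 0.19) and the guanylate binding protein gene Gbp2 2.69-fold (1.43 ± 0.19). Gvin1 and Gbp2 rose by 1.61 and 1.45 in experiment I and by 1.57 and 1.41 in experiment II. Vpreb3, a B cell gene, was 1.63-fold lower (-0.70 ± 0.11) and Fcer2a 1.42-fold lower (-0.51 ± 0.12).

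Limma called 188 genes in this comparison, 161 higher and 27 lower, and 187 had the same sign in both experiments. The excess of higher genes depended on the setting, with 371 higher and 273 lower under array weights and 363 and 314 in experiment II alone. Experiment I alone gave 18 calls, and of the 677 of experiment II alone 590 had the same sign in experiment I. Type I interferon genes rose in 13 of 45 cases (21 adjusted over the list alone), including Oas1g (0.82 ± 0.10), Oas2 (0.77 ± 0.11) and Usp18 (0.56 ± 0.08). Interferon-gamma-inducible genes rose in 13 of 31 cases (19 rose and 1 fell adjusted over the list alone), including Irgm2 (0.82 ± 0.10) and Gbp7 (0.73 ± 0.09), at a median of 0.23. Granule genes rose in 7 of 22 cases (12 adjusted over the list alone), with Ltf at 1.51 ± 0.23, Camp at 1.38 ± 0.21, Ngp at 1.27 ± 0.16 and Prtn3 at 1.16 ± 0.17. Mature neutrophil genes rose in 9 of 25 cases (16 adjusted over the list alone), such as Fpr2 (1.15 ± 0.17), S100a9 (1.04 ± 0.17) and Stfa1 (0.96 ± 0.14), and monocyte and macrophage genes in 4 of 28 (9), such as Fcgr4 (1.08 ± 0.16), Ly6c1 (0.78 ± 0.15) and the high affinity Fc receptor Fcgr1 (0.62 ± 0.07). Ms4a6d (1.32 ± 0.18) rose too, and the metallothionein Mt1 was 2.82-fold higher. These 5 lists kept their camera call with an estimated correlation.

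Another 5 lists lost their call in blood over both days. B cell genes fell in 2 of 19 cases (10 adjusted over the list alone, adjusted p = 0.0737 with an estimated correlation), and Cd5 was the 1 of 23 T cell genes that fell (-0.20 ± 0.05; 2 adjusted over the list alone, adjusted p = 0.354 with an estimated correlation). Inflammatory genes rose in 3 of 35 cases (6 adjusted over the list alone, adjusted p = 0.0587 with an estimated correlation), namely Socs3 (0.65 ± 0.12), Saa1 (1.10 ± 0.28) and Tnfaip2 (0.48 ± 0.13). The acute phase genes Saa1 and Saa2 rose by 2.17 and 2.51 in experiment I and by 0.04 and 0.03 in experiment II. Complement (adjusted p = 0.401 with an estimated correlation) and exocrine pancreas (median -0.19, adjusted p = 0.589 with an estimated correlation) had 0 called genes. Fas (0.30 ± 0.05), S1pr2 (0.15 ± 0.04) and Ier3 (0.51 ± 0.12) rose outside the called lists. Cell cycle, erythroid and platelet genes, which differed in spleen, had 0 of 49, 0 of 40 and 0 of 24 genes called in blood. Pancreatic transcripts exceeded the same limit in 7 blood arrays, 5 wild type and 2 mutated, all of experiment I. Without them 261 genes were called, 163 higher and 98 lower, 8 of 45 type I interferon, 11 of 31 interferon-gamma, 7 of 22 granule and 4 of 25 mature neutrophil genes rose, and the mature neutrophil list had adjusted p = 0.101 with an estimated correlation.

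At day 15, Gbp2 was already 3.04-fold higher in mutated blood (1.60 ± 0.26, n = 12 per genotype, adjusted p = 0.0014). Gvin1 (1.53 ± 0.27), Oasl2 (1.42 ± 0.27), the GTPase Irgm2 (0.96 ± 0.15), the myeloid gene Aif1 (0.89 ± 0.13), Fpr2 (1.10 ± 0.24) and Ly6c1 (0.96 ± 0.22) rose, with the same sign in both experiments. Lcn2 rose by 1.63 ± 0.37, but by 3.17 in experiment I and by 0.09 in experiment II. Brap (-0.41 ± 0.08) and Ncf1 (-0.48 ± 0.10) were the 2 genes that fell among 24 called. Experiment I alone gave 1 call and experiment II alone 445, 226 higher and 219 lower, of which 220 had the same sign in experiment I. In the direction of experiment II, the median change of these 445 genes in experiment I was -6.4e-04. As a set they thus did not carry over. Type I interferon genes rose in 5 of 45 cases (14 adjusted over the list alone) and interferon-gamma genes in 5 of 31 (16), while granule, mature neutrophil and monocyte lists had 1 gene each (7, 12 and 9 adjusted over the list alone). Camera called 8 lists and 6 with an estimated correlation, the inflammatory list among them (0 genes called, 4 adjusted over the list alone). The MHC class II list had adjusted p = 0.215 with an estimated correlation, and the pancreas list, with a median of -0.51, adjusted p = 0.134 with an estimated correlation. Without the arrays with pancreatic transcripts 15 genes were called, with 0 of 45 type I interferon and 4 of 31 interferon-gamma genes higher, and the mature neutrophil list had adjusted p = 0.366 with an estimated correlation.

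At day 44, granule and B cell genes differed in blood. Lcn2 was 5.51-fold higher (2.46 ± 0.37, n = 12 per genotype, adjusted p = 4.8e-05), the glycoprotein gene Lrg1 4.3-fold (2.10 ± 0.35), and Ltf (1.83 ± 0.32), Camp (1.69 ± 0.30) and Ngp (1.59 ± 0.23) rose as well. Vpreb3 was 2.17-fold lower (-1.12 ± 0.16), and Fcrla (-0.83 ± 0.17), Fcer2a (-0.83 ± 0.18) and the kinase Blk (-0.83 ± 0.18) fell. Limma called 238 genes, 113 higher and 125 lower, with 0 in experiment I alone (795 at an unadjusted p under 0.05) and 923 in experiment II alone, of which 823 had the same sign in experiment I. B cell genes fell in 9 of 19 cases (15 adjusted over the list alone) at a median of -0.59, and granule genes rose in 7 of 22 (11) at a median of 0.45. Type I interferon genes such as Oas1g (0.94 ± 0.14) rose in 8 of 45 cases (17 adjusted over the list alone), interferon-gamma genes such as Gbp7 (0.71 ± 0.13) in 5 of 31 (13) and monocyte genes such as Fcgr1 (0.78 ± 0.11) in 2 of 28 (5). Mature neutrophil genes such as Stfa1 (1.41 ± 0.20) rose in 4 of 25 cases (14 adjusted over the list alone, adjusted p = 0.0554 with an estimated correlation). Cd2 was the 1 T cell gene that fell (-0.63 ± 0.17; list adjusted p = 0.392 with an estimated correlation). The erythroid and cell cycle lists each had adjusted p = 0.661 with an estimated correlation. Without the arrays with pancreatic transcripts 325 genes were called, and adjusted p with an estimated correlation was 0.0543 for the interferon-gamma and B cell lists and 0.0581 for the monocyte list, against 0.0252 for each with all arrays.

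The days shared 17 higher genes in blood against 0.15 expected if independent, and 1 lower gene against 0.0151. That lower gene was Ncf1, the mutated gene itself, so it says nothing of a fall shared by other genes. As in spleen, both days came from 1 fit, so their calls are linked. The genotype by day interaction called 1 gene, Zfp873 (-0.42 ± 0.08, adjusted p = 0.0466), a zinc finger gene whose genotype difference was 0.18 at day 15 and -0.24 at day 44. The next 4 genes did not pass, namely Fam168b (-0.52 ± 0.10), Drg1 (-0.57 ± 0.12), Senp3 (-0.46 ± 0.10) and Slc30a5 (-0.42 ± 0.09). Trend and robust eBayes called 0 genes, and experiment II alone 690. The interaction called 5 lists with camera and 0 with an estimated correlation. Among them the B cell list had a median of -0.57 (adjusted p = 0.262 with an estimated correlation), so a change of its genotype effect between the days was not established. The granule and MHC class II lists each had adjusted p = 0.369, the pancreas list adjusted p = 0.406 and the erythroid list adjusted p = 0.879 with an estimated correlation.

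Between day 15 and day 44 limma called 13 genes in blood, 10 higher and 3 lower, but 2 genes with trend and robust eBayes (Pdrg1 and Cog8) and 0 without the experiment term. The granule gene Ngp rose by 0.76 ± 0.16 (n = 24 per day, adjusted p = 0.0464), the stefin Stfa1 by 0.68 ± 0.14, the lectin Clec4a1 by 0.59 ± 0.13, the inhibitory Fc receptor Fcgr2b by 0.32 ± 0.06 and Pdrg1 by 0.31 ± 0.05. Cog8 (-0.37 ± 0.07), Hdgf (-0.26 ± 0.06) and the repair helicase Ercc3 (-0.28 ± 0.06) fell. Experiment I alone gave 0 calls (1339 at an unadjusted p under 0.05) and experiment II alone 796, of which 398 had the same sign in experiment I. As a set these 796 genes thus did not carry over. Granule genes rose in 1 of 22 cases (9 adjusted over the list alone), and theirs was the 1 of 9 camera calls that remained with an estimated correlation (adjusted p = 0.0409). The mature neutrophil, T cell, erythroid, cell cycle and MHC class II lists each had adjusted p = 0.733, the plasma cell list 0.244, complement 0.64 and ER stress 0.709 with an estimated correlation.

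The genotype effects of the tissues were compared within mice, as the difference of spleen and blood of each mouse. The genotype difference was higher in spleen for Ctsg (1.82 ± 0.21, n = 24 per genotype, adjusted p = 9.9e-08), Mpo (1.75 ± 0.20), Elane (1.62 ± 0.21), Ms4a3 (1.46 ± 0.18) and the erythroid genes Hemgn (1.26 ± 0.22) and Tal1 (1.21 ± 0.20). Ctsg, Mpo and Ms4a3 lay below the blood array median of 6.20 in both genotypes, at 6.14, 6.08 and 5.99 in mutated mice, so for these genes the values show a change in spleen and not the size of a difference between the tissues. Gbp2 (-1.09 ± 0.17), Aif1 (-1.02 ± 0.11), Gvin1 (-1.02 ± 0.17), the chemokine Cxcl9 (-0.79 ± 0.15) and Ifit3 (-0.54 ± 0.10) differed the other way, with the genotype difference lower in spleen than in blood. Ncf1 had -0.31 ± 0.09 (adjusted p = 0.0343), with -0.50 in experiment I and -0.12 in experiment II. Background may have limited the fall in experiment I, so a larger fall in spleen was not established. Limma called 682 genes, 476 higher and 206 lower in spleen than in blood, against 565 and 443 in experiment II alone, 708 and 470 with array weights and 307 and 69 without the experiment term. Of the 682 genes 550 were called in spleen and 75 in blood, and although 485 had opposite signs in the tissues, only 3 were called in both with opposite signs. Granule genes were higher in 10 of 22 cases (12 adjusted over the list alone), erythroid genes in 23 of 40 (31) and cell cycle genes such as Mcm2 (0.83 ± 0.13) and Rrm2 (0.93 ± 0.16) in 35 of 49 (40). Lower were 6 of 45 type I interferon genes (13 adjusted over the list alone), 9 of 31 interferon-gamma genes, 4 of 28 monocyte genes including Cd14 (-0.70 ± 0.18) and Fcgr1 (-0.49 ± 0.10), 3 of 15 germinal centre genes and 6 of 23 T cell genes including Cd8b1 (-0.59 ± 0.16) and Lef1 (-0.45 ± 0.10). Saa2 (-1.29 ± 0.28) and Mt1 (-1.09 ± 0.28) were lower too, at -2.52 and -1.82 in experiment I and at -0.06 and -0.37 in experiment II, and spleen Saa2 lay below the array median. Camera called 15 lists and 8 with an estimated correlation. Adjusted p with an estimated correlation was 0.142 for the inflammatory and stroma lists, 0.17 for the NADPH oxidase and MHC class II lists, 0.405 for B cells, 0.515 for platelets and 0.606 for the pancreas list. Without the arrays with pancreatic transcripts 634 genes were called and the granule, erythroid and cell cycle lists had 9 of 22, 26 of 40 and 28 of 49 genes higher, while the type I interferon list had adjusted p = 0.220 the T cell list 0.126 and the interferon-gamma, monocyte and germinal centre lists each 0.120 with an estimated correlation.

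Spleen and blood over both days shared 59 higher genes against 9.11 expected if independent and 17 lower genes against 1.32, but both tissues came from the same 48 mice, so independence is not the value expected without a shared effect. Across the 1857 genes called in either tissue, which are not independent replicates, the effects correlated at r = 0.38.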

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

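The tests of a lower share of lymphocytes, of a larger spread in experiment II, of the axis between the experiments in separate mice and of splits within the experiments were chosen only after the result was seen, as was the removal of arrays with pancreatic transcripts as an alternative.

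The genotype effect differed between spleen and blood for 682 genes, and between the days in blood for 1 gene, Zfp873 (-0.42 ± 0.08). Genotype effects differed between the experiments for 2 genes in blood, and day effects for 2457 genes in spleen and 25 in blood. Among probes with no gene named here, which no comparison used, 128 were called for the genotype in spleen over both days and 15 in blood. The most significant were ILMN_2669172 in spleen (0.66 ± 0.08) and ILMN_2742861 in blood (1.20 ± 0.15).

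The rise of granulocyte precursor, erythroid and cell cycle genes with lower lymphocyte genes in mutated spleen was weighed first. For the granule genes, pancreatic tissue in some spleen arrays was argued against, as their median over both days was 1.30 without these arrays and 1.32 with them. At day 15, however, 33 genes were called without these arrays against 410 with them, and most erythroid and cell cycle genes lost their call. Most granule genes lost their call there too while their median held, so lost calls do not set these lists apart. The medians of the erythroid and cell cycle lists without these arrays are not given here. For the erythroid and cell cycle genes this explanation therefore stays open. A lower share of lymphocytes alone would raise all other cell types alike, but the granule median exceeded that of the monocyte and macrophage list by 1.38. A list median also depends on how many of its genes are dim or shared between cell types, so unequal medians do not exclude a lower lymphocyte share. Per mouse, the mean of the granule genes minus that of the monocyte genes was higher by 1.19 ± 0.13 in the 24 mutated than in the 24 wild type mice; both medians had been seen before, so no p is given. An effect of a single experiment was argued against by the granule medians, the lower of which was 1.19 in experiment II, and by T cell medians of -0.47 and -0.46. A candidate explanation that stays open is more blood cell formation in the spleen of mutated mice, since cell counts and histology were not used here and a change in transcripts per cell was not tested.

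The rise of interferon-induced genes in mutated blood was weighed next. An effect of a single experiment was argued against, as the type I interferon median was 0.19 in experiment I and 0.111 in experiment II, with camera adjusted p of 6.7e-23 and 6.3e-17. Both p rest on the preset correlation of camera, and those with an estimated correlation are not given per experiment. With each array's monocyte and mature neutrophil scores as covariates the median over the list fell from 0.145 to 0.0579, below the limit set beforehand. Over the 13 list genes called in blood, picked by their rise in these data, the median fell only from 0.534 to 0.403. More monocytes and neutrophils in mutated blood may thus account for a part of the rise, and the size of that part was not settled. Camera still gave an adjusted p of 1.4e-04 for the list. Higher interferon signalling per cell was not tested and stays open, as does interferon acting on the genes that make up the scores.

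Day effects of spleen in experiment I and not in experiment II were the third pattern. A larger spread in experiment II was argued against, as the residual SD was 0.135 there and 0.141 in experiment I, and the day by experiment term called 2457 genes. A processing difference along the axis that separates the experiments stays open. Across genes the day effect in experiment I correlated with the difference between experiments at r = -0.597, but a real change with time in experiment I alone would also give a negative r. Next, the difference between experiments was taken at day 15, from mice of experiment I other than those of the day effect. Over 100 halvings of the mice r then lay between -0.575 and 0.0786, with a median of -0.367, which does not decide. Genes are not independent replicates, and the dates of sampling and RNA isolation are not given in the sources used here. A biological change with time in 1 experiment is not excluded.

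Other splits of the samples are given as the number of 100 splits, the real one included, that called as many genes. For spleen these were 2 at day 15 (real 410, highest other 856), 1 at day 44 (861, 163), 1 over both days (1748, 2) and 1 for the day (3799, 1). For blood they were 2 at day 15 (24, 1096), 1 at day 44 (238, 1), 2 over both days (188, 704), 2 for the day (13, 20) and 3 for the interaction (1, 1), and for spleen against blood 1 (682, 1). With 100 splits no share under 1 in 100 can be seen, so these counts make chance unlikely without excluding it. The 1 gene of the blood interaction was lost in several settings, so no weight is put on it. The 13 genes of the day in blood became 0 without the experiment term and 2 with trend and robust eBayes. For the interaction in spleen all 100 splits called at least the real 0, with 1398 in the highest. Single splits that called several times the real number point to a structure of the samples. These splits did not keep the groups balanced over the experiments, as the real ones are. Among 100 splits within the experiments the highest other counts were 1 at day 15, 152 at day 44, 339 over both days and 2 for the day in spleen, 0, 1, 1 and 1 in blood, and 87 for spleen against blood, and in each of these comparisons only the real split called as many genes as it did. For the blood interaction 4 of these splits called at least 1 gene, with 1259 in the highest, and for the interaction in spleen the highest called 23. The cause of the high counts was not established.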

How the results depend on the processing

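The normexp offset, the removal of arrays with pancreatic transcripts and the experiment by group terms were chosen only after the data were seen. Counts of called genes moved by more than 1.5 times as follows, and the cause was not tested. Values are for spleen at day 15 (410), day 44 (861), over both days (1748) and by day (3799), for blood at day 15 (24), day 44 (238), over both days (188), by day (13) and interaction (1), and for spleen against blood (682). Without the experiment term they were 146, 427, 1067 and 1722 in spleen, 8, 51, 76, 0 and 0 in blood, and 376. Each experiment alone has 24 of the 48 mice, and in blood the residual SD was 0.160 in experiment I and 0.114 in experiment II. Experiment I alone gave 142, 52 and 581 for the genotype in spleen, 1, 0, 18, 0 and 0 in blood, and 32. Experiment II alone gave 2 at day 15 and 1 by day in spleen and 445, 923, 677, 796 and 690 in blood. The compared groups alone gave 244 in spleen at day 15. Without arrays with pancreatic transcripts spleen had 33 at day 15 and 1719 by day, and blood 15 at day 15, 27 by day and 2 for the interaction. In blood, every probe gave 42, 22 and 3 at day 15, by day and for the interaction. Genes above the median level gave 370, 34 and 0 at day 44, by day and for the interaction, and trend and robust eBayes 2 and 0 by day and for the interaction. Array weights gave 51, 731, 644, 152 and 13 in blood and 1178 for spleen against blood. Over both days in blood the 161 higher and 27 lower genes became 371 and 273 with array weights, 363 and 314 in experiment II alone and 163 and 98 without arrays with pancreatic transcripts. With the mouse as a random block blood had 39, 43 and 5 at day 15, by day and for the interaction, and experiment by group terms gave 37 and 0 by day and for the interaction.

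The lists were followed over the genotype and day comparisons within a tissue, without the interactions and spleen against blood. In experiment II alone 8 list medians reversed. The exocrine pancreas list had 0.0842 at day 15, 0.017 at day 44 and 0.0619 over both days in spleen and 0.0058 over both days in blood, and the arrays with pancreatic transcripts are all of experiment I. By day, interferon-gamma had 0.017 in spleen, and type I interferon -0.0356, erythroid -0.113 and cell cycle -0.0236 in blood. In these comparisons 165 list results kept their side of the threshold with an estimated correlation and 51 of the calls ended, and with fry 187 did, 27 ended and 2 were gained. Of the named gene results 210 kept their side without arrays with pancreatic transcripts, 176 without the experiment term, 122 in experiment I and 177 in experiment II, and 0 reversed in any setting. A part of these genes had been picked for the same sign in both experiments, which favours this. Quantile normalisation again and centring moved nothing, since the arrays already share a distribution, and so test nothing. No paired analysis was possible because the genotypes are different mice and the replicate numbers of the groups pair nothing; mice were paired for spleen against blood only. Intensities near the floor of about 45 to 46 limit what can be seen for dim genes, such as the second probe of Ncf1.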

Other observations

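The tests of basophil and eosinophil genes, of the neighbours of Ncf1 and of pancreatic carry-over were chosen only after the result was seen.

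In mutated spleen 4 of 11 measured genes of basophils, mast cells and eosinophils rose. The eosinophil granule gene Prg2 rose by 1.13 ± 0.14, the basophil protease Prss34 by 0.89 ± 0.09, the eosinophil peroxidase Epx by 0.58 ± 0.08 and the IgE receptor chain Fcer1a by 0.19 ± 0.06. The mast cell genes Cpa3 (0.08 ± 0.06) and Ms4a2 (0.05 ± 0.04) and 5 others did not pass, 0 fell, and the median was 0.192, with 0.26 in experiment I and 0.08 in experiment II. The list was drawn up after Prss34 and Epx had been seen to rise, so it cannot serve as a test. Without these 2 the median of the other 9 genes was 0.0803 (p = 0.00188 in experiment I and 0.0194 in experiment II with an estimated correlation), but these genes were also picked after the result. Whether basophils and eosinophils move with the granulocyte precursors stays open.

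Granule scores of spleen and blood were related across mice of each genotype, after removal of experiment and day means. In 24 wild type mice r was 0.677 (permutation p = 2.9e-04, adjusted over 6 relations 0.0014; rho 0.729, p = 1e-04) and 0.697 without the 2 farthest mice, with 0.738 and 0.788 in experiments I and II. In 24 mutated mice r was 0.610 (p = 4.7e-04, adjusted 0.0014; rho 0.713, p = 1.3e-04) and 0.586 without the 2 farthest mice, with 0.583 and 0.725 in the experiments. Type I interferon scores were related in wild type mice, with r = 0.549 (p = 0.00548, adjusted 0.011; rho 0.585, p = 0.00291), 0.464 without the 2 farthest mice, and 0.572 and 0.771 in the experiments. In mutated mice their r was 0.0264 (p = 0.903, adjusted 0.903; rho 0.0739, p = 0.732) and 0.324 without the 2 farthest mice, with -0.284 in experiment I and 0.712 in experiment II. T cell scores had r = 0.0804 in wild type mice (p = 0.708, adjusted 0.849; rho 0.0626, p = 0.769), 0.0434 without the 2 farthest mice, and 0.235 and -0.572 in the experiments. In mutated mice T cell r was 0.373 (p = 0.0728, adjusted 0.109; rho 0.368, p = 0.0772), 0.301 without the 2 farthest mice, and 0.340 and 0.540 in the experiments. An adjusted p over 0.05 in 24 mice had been set as counting against a relation, but it excludes none of moderate size, so the last 3 relations stay open. Whether r differed between genotypes was not tested.

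Variants carried along with the Ncf1 locus could change neighbouring genes. Of the 50 measured genes on each side of Ncf1 in the gene order of assembly GRCm38.p6, 15 of 100 were called in spleen over both days, against 10.5% of the other genes (one-sided Fisher exact p = 0.101), which leaves the question open. The adjacent genes Gtf2ird2 (-0.10 ± 0.06) and Gtf2i (0.02 ± 0.03) were not called, while Castor2 (-0.16 ± 0.04) and Lat2 (-0.38 ± 0.08), a few genes away, fell. In blood Castor2 (0.05) and Lat2 (-0.07) were not called. Cldn15, at the far end of the 50 genes on its side, rose in spleen by 0.56 ± 0.07.

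Pancreatic transcripts in 7 blood arrays could reflect carry-over from the spleen sample of the same mouse. Across the 24 mice of experiment I the pancreas scores of spleen and blood had rho = 0.0409 (permutation p = 0.851) and r = 0.178 (p = 0.430), and r was -0.223 without the 2 farthest mice. Only 1 mouse exceeded the limit in both tissues, and 24 mice do not exclude a weak relation.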
